A study of Brassica napus with 3 samples.

How the data were processed

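Chromatin from leaf tissue of Brassica napus (canola, an allotetraploid with an A subgenome related to B. rapa and a C subgenome related to B. oleracea) was immunoprecipitated with an antibody against trimethylated lysine 4 of histone H3 (H3K4me3), a mark that sits on the nucleosomes at the start of transcribed genes. Per the labels' protocols, leaf 4 was taken from plants 26 days old, 1.5 g of powdered tissue was used, and the ChIP was native: nuclei were digested with 30 U of micrococcal nuclease for 10 minutes without crosslinking, and the released mononucleosomes were incubated with 2.5 ug of antibody. The series holds 3 libraries. One is a control-line library made without antibody, one is H3K4me3 from the control line, and one is H3K4me3 from PEG1, a selected epiline of the same cultivar. The labels give 1 library per line and no replicate. The 2 H3K4me3 libraries are covered by 4 lists of peak summits, each line being listed once against a B. rapa reference and once against a B. oleracea reference. Values of the no-antibody library were not analysed here.

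Each list gives the position of a summit, a peak name and a score. Peaks came from MACS2 version 2.0, per the submitters' processing notes. The aligner, the treatment of reads that fit both references, the use of the no-antibody library as background and any filter are not given in the sources used here. The deposited scores are on a −log10 scale of significance as the authors' peak caller gave them. Whether they are p-values or q-values is not stated; none was a whole number, and the lowest score of every list lay just above the −log10 of 0.05. Because the score depends on the depth of a library, which is unknown here, scores were compared within a list, and between lines only as ranks of shared summits. Scores and ranks set side by side for both lines are not read as a change of the mark. Every peak carried 1 summit, and the boundaries of the peaks were not used here, so a broad domain called as 1 peak in one line and as 2 in the other gives different numbers of summits. Because each library was listed against both references, a read from one subgenome may have supported a summit on both, and the A and C results are not independent of each other.

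Per the sequence names, the B. rapa coordinates are those of the BGI pseudochromosomes version V1 of BR5307, numbered 1 to 11, and the B. oleracea coordinates those of the BGI scaffolds version V2 of TO1000, which are named here by the code that ends each scaffold name. Positions are 1-based. An annotation of these builds was not used here, and the gene table at hand belongs to another assembly, so summits were not assigned to genes and the planned counts of marked genes and of gene lists were not made. Regions are named by coordinates.

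A summit counted as shared when a summit of the other line lay within 150 bp. Summits of a list within 500 bp of each other were joined to regions, and a region counted as shared when a region of the other line overlapped it or lay within 500 bp. The chance level came from 100 circular shifts of the other list, each sequence being moved by 10 to 90% of the span its summits cover. Line-specific regions were counted among equally long lists: as many best-scored summits of each list as the shorter list holds, with no summit of the full other list within 500 bp. Regions per 500 kb window were compared where both lines together had at least 50. Shares carry 95% Wilson intervals, window shares exact binomial intervals, and ratios of counts exact conditional intervals. All of these cover counting error only. Intervals of ratios and window shares treat the counts of the lines as independent, although most regions are shared, and are therefore wider than the scatter between windows. With 1 library per line no difference has a replicate check, no test between lines was possible and no p-value is given. The computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The matching was tested on simulated data: in a second list made from the 27672 control summits on the B. rapa reference, 100% of the shared and 100% of the added summits were recovered, and the same percentages were recovered from the 36371 control summits on the B. oleracea reference. The simulated shared summits were moved by less than the matching distance, and the added ones lay far from any control summit. Full recovery was therefore built in. It checks the computation and not how well real summits are matched.

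The groups, the matching distances, the alternatives and the rule for named regions were fixed before the data were examined. The rule took, per reference, the 5 best-scored summits of each list, the 5 line-specific regions with the most summits in each direction (ties by best score), and the 3 windows with the highest and the 3 with the lowest share of PEG1 regions. The alternatives were other matching distances, other window sizes, only the better-scored part of each list, equally long lists, summits in place of regions and regions of at least 2 summits. Leaving out B. rapa pseudochromosome 11 and the settings of the runs of line-specific summits were added after the data were seen.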

Results

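The data describe where H3K4me3 lay in leaf chromatin of a control canola line and of PEG1, a line selected from the same cultivar, and the series asks how that selection altered the distribution of the mark. One library of each line was available. The control library gave 27672 summits on the 11 B. rapa pseudochromosomes and 36371 summits on 1244 B. oleracea scaffolds. The PEG1 library gave 31464 summits on the same 11 pseudochromosomes and 40707 summits on 1273 scaffolds. Read depth is unknown for both libraries. The median score was 14.4 in the control list and 18.5 in the PEG1 list on B. rapa, and 16.5 and 21.2 on B. oleracea.

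The PEG1 lists were longer than the control lists on both references. PEG1 had 3792 more summits than the control on B. rapa, a ratio of 1.14 (95% interval 1.12 to 1.16), and 4336 more on B. oleracea, a ratio of 1.12 (1.10 to 1.14). After joining neighbouring summits, 31153 regions in PEG1 stood against 27486 in the control on B. rapa, and 40380 against 36191 on B. oleracea. Almost all regions held a single summit: between 0.492% and 0.985% of the regions of a list held 2 or more. Neighbouring summits lay a median of 5922 bp apart in the control and 5256 bp apart in PEG1 on B. rapa, and 6464 and 5828 bp apart on B. oleracea. No pair was closer than 247 bp. Between 100 and 400 bp only 17 to 43 neighbouring pairs per list were found, and the fullest 10 bp bin began at 390 bp in 3 of the lists and at 370 bp in the B. oleracea control list, with 4 to 13 pairs in 3 lists and 18 in the B. oleracea PEG1 list. The search ended at 400 bp, so the bin at 390 bp is the last one searched. It is not read as a preferred spacing.

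Most of the marked regions were found in both lines, and most of what differed was on the PEG1 side. On B. rapa, 92.3% of the control regions (91.97 to 92.6) had a PEG1 region within 500 bp, against 10.9% under random shifts of the PEG1 list. In the other direction 81.4% of the PEG1 regions (80.97 to 81.8) had a control region, against 9.68% under shifts. On B. oleracea the shares were 91.1% of control regions (90.8 to 91.4) and 81.6% of PEG1 regions (81.3 to 82.02), with chance levels of 9.998% and 8.98%. Shared regions numbered 25367 seen from the control and 25360 seen from PEG1 on B. rapa, and 32973 and 32968 on B. oleracea. The lower PEG1 shares therefore restate the longer PEG1 lists. The positions of the summits themselves were also close. Within 150 bp of each other lay 21881 summits on B. rapa, 79.1% of the control and 69.5% of the PEG1 list, and 28084 on B. oleracea, 77.2% and 68.99%. Random shifts gave between 2.75% and 3.36% at that distance. These shares depend on the distance allowed: within 50 bp the control shares were 56.9% on B. rapa and 54.8% on B. oleracea.

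The strongest summits of each line had a summit of the other line close by, but the sets of strongest summits coincided only in part. Of the 276 best-scored control summits on B. rapa, 52.2% had one of the 276 best-scored PEG1 summits within 500 bp. On B. oleracea it was 49.9% of 363. Among the best-scored 10% the shares were 64.0% and 62.4%. All 5 best-scored summits of each list had a summit of the other line within 60 bp on B. rapa and within 30 bp on B. oleracea, and 2 of the 5 on each reference were among the best 5 in both lines. On B. rapa these were the summit on pseudochromosome 2 at 17186009 in the control (score 107.2) and 17185973 in PEG1 (137.1), and that on pseudochromosome 11 at 2369631 in the control (119.3) and 2369649 in PEG1 (126.3). The other strong B. rapa control summits lay on pseudochromosome 5 at 17614991 (score 118.9) and 6147339 (107.02) and on pseudochromosome 7 at 10960267 (105.8), and the other strong PEG1 summits on pseudochromosome 11 at 11632103 (130.8), pseudochromosome 7 at 11921875 (128.8) and pseudochromosome 8 at 15198273 (122.8). On B. oleracea the common ones lay on scaffold ERB29584 at 471252 in the control (122.7) and 471241 in PEG1 (122.6), and on scaffold ERB29523 at 213936 in the control (119.2) and 213921 in PEG1 (137.2). The remaining control summits lay on scaffolds ERB31285 at 411 (114.04), ERB29809 at 208335 (111.8) and ERB29427 at 564845 (111.5). The remaining PEG1 summits lay on scaffolds ERB29860 at 271569 (131.7), ERB29962 at 76985 (124.1) and ERB29523 at 535657 (124.01).

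Summits found in 1 line only were mostly weak. Of those with no summit of the other line within 500 bp, 15.5% in the control and 8.14% in PEG1 scored above the median of their list on B. rapa, and 13.9% and 7.91% on B. oleracea. Each list was divided by score into 4 classes of equal size. In the weakest class of the B. rapa PEG1 list, 53.5% of the summits (52.4 to 54.6) had no control summit within 500 bp, and in the strongest class 1.83% (1.56 to 2.15). The corresponding control shares were 19.9% (19.01 to 20.9) and 1.76% (1.48 to 2.10). On B. oleracea the PEG1 share was 54.7% (53.7 to 55.7) in the weakest and 2.08% (1.82 to 2.38) in the strongest class, and the control share 25.3% (24.4 to 26.2) and 1.98% (1.71 to 2.29). Control classes were matched to the longer PEG1 list, so the contrast between the lines in the weakest class cannot be separated from list length. At a distance of 2000 bp the strongest classes held 5 unmatched summits among 7866 in PEG1 and 1 among 6918 in the control on B. rapa, and 3 among 10177 and 1 among 9093 on B. oleracea. The median score of shared regions exceeded that of line-specific regions in every list: 15.3 against 5.73 in the control and 21.8 against 6.28 in PEG1 on B. rapa, and 17.9 against 5.25 and 25.4 against 6.03 on B. oleracea.

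**Figure D1:**
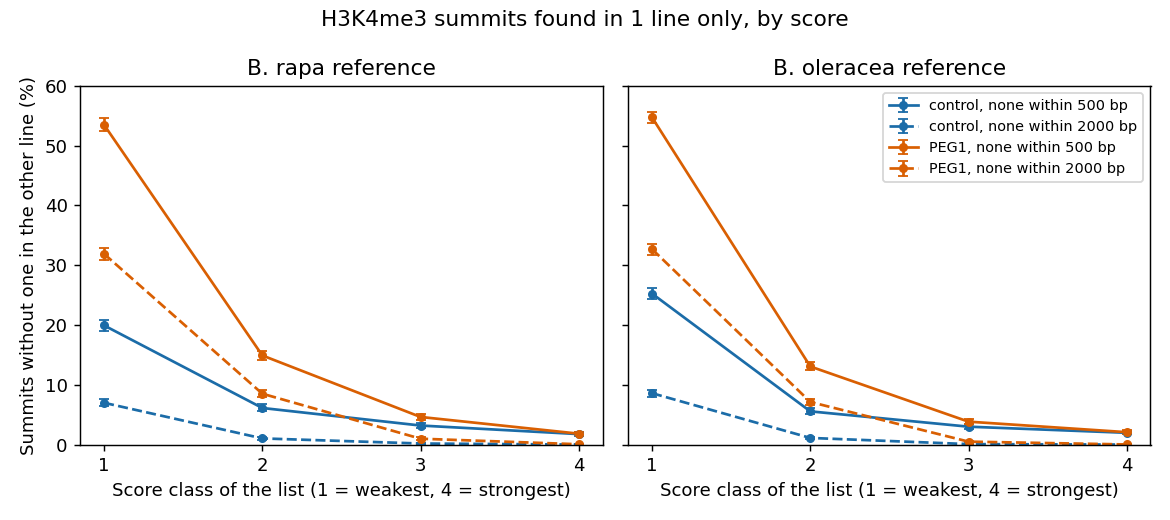
Percentage of summits with no summit of the other line within 500 bp (solid lines) or 2000 bp (dashed lines), for the 4 equal classes of each list ordered by peak score; blue is the control, orange PEG1, and bars are 95% Wilson intervals covering counting error only. In the weakest class 53.5% of B. rapa and 54.7% of B. oleracea PEG1 summits were unmatched at 500 bp, and in the strongest class 1.83% and 2.08%. Control summits were matched to the longer PEG1 list, so the gap between the lines cannot be separated from list length.

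Line-specific regions were also counted among the best-scored summits of each list, as many as the control list holds, each set being matched to the full list of the other line. On B. rapa 3329 of 27503 PEG1 regions, 12.1% (11.7 to 12.5), had no control summit within 500 bp, against 2119 of 27486 control regions, 7.71% (7.40 to 8.03), with no PEG1 summit. On B. oleracea the counts were 4486 of 36170 PEG1 regions, 12.4% (12.1 to 12.7), and 3218 of 36191 control regions, 8.89% (8.60 to 9.19). Requiring 2000 bp reduced them to 1782 and 570 on B. rapa and to 2382 and 890 on B. oleracea, in the same order. The control list was thereby used whole and the PEG1 list down to a score of 5.36 on B. rapa and 5.02 on B. oleracea, and control regions had the longer list to match. With 0.5 times as many summits from each list the counts were 382 in PEG1 and 338 in the control on B. rapa, and 496 and 451 on B. oleracea. With both lists cut to equal length, a setting that forces the shares together, 87.9% of PEG1 and 88.06% of control regions were shared on B. rapa and 87.6% of each on B. oleracea. The counts of line-specific regions do not show an excess in PEG1 that can be separated from the length of its list. Control regions had the longer list to match, and how far that lowered their counts was not measured. The shares at equal length do not bear on this.

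Few line-specific regions held more than 1 summit. On B. rapa there were 6 in PEG1 and 4 in the control, and on B. oleracea 8 and 11. The PEG1 regions on B. rapa with the best scores among these lay on pseudochromosome 6 from 16660457 to 16660943 (best score 19.96, nearest control summit 6576 bp away), pseudochromosome 5 from 17857646 to 17858120 (17.7, 3940 bp), pseudochromosome 10 from 13321761 to 13322246 (12.3, 2107 bp), pseudochromosome 9 from 4799988 to 4800426 (12.3, 826 bp) and pseudochromosome 4 from 21317108 to 21317507 (9.47, 5992 bp). On B. oleracea they lay on scaffolds ERB29360 from 303686 to 304120 (38.3, 766 bp), ERB30334 from 14411 to 14875 (24.1, 18440 bp), ERB29525 from 519789 to 520249 (18.4, 18831 bp), ERB29475 from 678111 to 678503 (13.2, 4638 bp) and ERB29712 from 129370 to 129820 (12.7, 4898 bp). Thus 4 of the 5 named PEG1 regions on each reference were over 2000 bp from any control summit.

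The control-specific regions named by the same rule lay nearer to summits of the other line, with 0 of 5 on B. rapa and 1 of 5 on B. oleracea over 2000 bp away. They were matched to the longer PEG1 list, whose summits lie closer together, so list length alone could give shorter distances. Those on B. rapa were on pseudochromosome 6 from 24879715 to 24880143 (best score 15.9, nearest PEG1 summit 722 bp away), pseudochromosome 10 from 14984670 to 14985090 (9.13, 690 bp), pseudochromosome 3 from 18891072 to 18891540 (9.13, 607 bp), pseudochromosome 7 from 8694355 to 8694729 (6.45, 523 bp) and pseudochromosome 9 at 15572883, a single summit (58.1, 745 bp). Those on B. oleracea were on scaffolds ERB29583 from 64089 to 64870, with 3 summits (7.69, 527 bp), ERB29354 from 1351051 to 1351426 (12.4, 4324 bp), ERB29429 from 542346 to 542799 (8.34, 683 bp), ERB29363 from 1245305 to 1245680 (6.84, 1658 bp) and ERB29323 from 2705974 to 2706434 (6.83, 671 bp).

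PEG1 had more regions than the control on each of the 11 B. rapa pseudochromosomes. The ratio of PEG1 to control regions lay between 1.12 and 1.17 on pseudochromosomes 1 to 10 and was 1.14 (1.07 to 1.22) on pseudochromosome 11. It was lowest on pseudochromosome 7, at 1.12 (1.06 to 1.18), and highest on pseudochromosome 4, at 1.17 (1.10 to 1.24). Between 87.7 and 118.7 control regions and between 102.7 and 133.2 PEG1 regions were found per Mb on pseudochromosomes 1 to 10. Pseudochromosome 11, whose make-up is not given in the sources used here, held 52.5 control and 60.01 PEG1 regions per Mb. B. rapa has 10 chromosomes, so this density is not read as that of a chromosome.

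**Figure D2:**
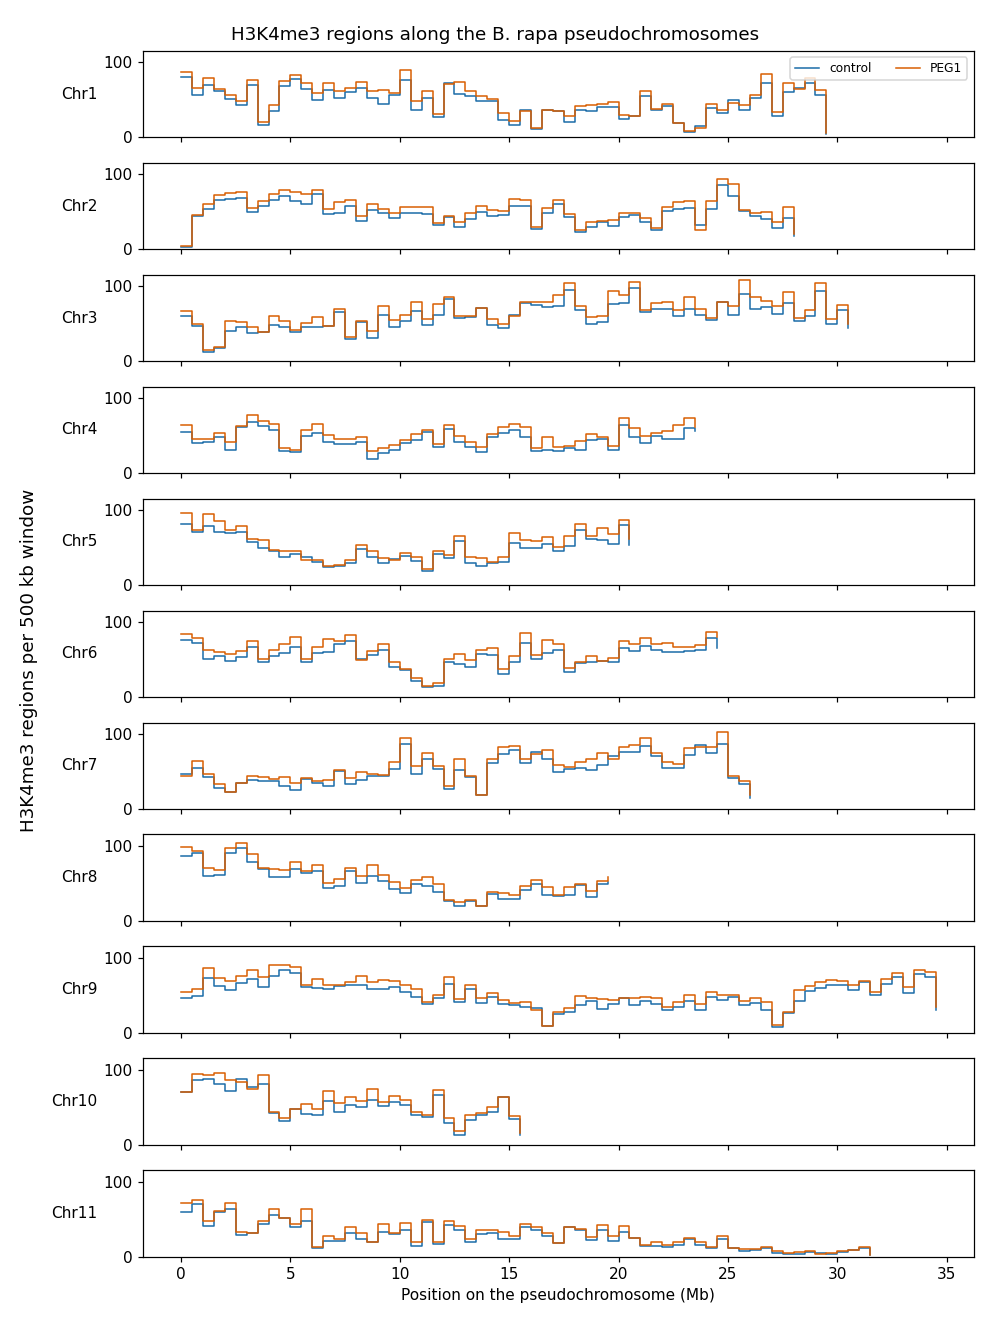
H3K4me3 regions per 500 kb window (vertical axes) along the 11 B. rapa pseudochromosomes (horizontal axis, Mb), with the control in blue and PEG1 in orange; the last window of a pseudochromosome can be shorter than 500 kb. The 2 lines follow the same profile, for example with 97 control and 105 PEG1 regions on pseudochromosome 3 from 20500001 to 21000000 and 9 in each on pseudochromosome 9 from 16500001 to 17000000.

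Among windows of 500 kb with at least 50 regions of both lines together, none held regions of 1 line only; 58 windows on B. rapa and 1168 on B. oleracea had fewer. Without that minimum no B. rapa window lacked either line, and the B. oleracea windows that lacked one line held at most 2 regions of the other. PEG1 held 53.1% of all regions of both lines on B. rapa, and over 520 windows its share had an SD of 1.93 percentage points, with a range of 44.8 to 60.8%. On B. oleracea the share was 52.7%, with an SD of 2.06 points over 626 windows and a range of 45.1 to 61.5%. Independent counts of this size would have spread by 5.01 and 5.63 points. The lowest PEG1 shares on B. rapa were on pseudochromosome 2 from 23500001 to 24000000 (26 PEG1 and 32 control regions), pseudochromosome 5 from 5500001 to 6000000 (33 and 37) and pseudochromosome 1 from 25000001 to 25500000 (46 and 50). The highest were on pseudochromosome 4 from 16500001 to 17000000 (48 PEG1 and 31 control regions), pseudochromosome 5 from 13500001 to 14000000 (36 and 25) and pseudochromosome 11 from 14500001 to 15000000 (33 and 23). On B. oleracea the lowest were on scaffolds ERB29323 from 3000001 to 3500000 (23 PEG1 and 28 control regions), ERB29547 from 500001 to 1000000 (28 and 33) and ERB29888 from 1 to 500000 (24 and 27), and the highest on scaffolds ERB29354 from 500001 to 1000000 (32 PEG1 and 20 control regions), ERB29846 from 1 to 500000 (34 and 23) and ERB29614 from 1 to 500000 (31 and 21). Among the short scaffolds, 43 carried PEG1 summits only, 50 in all, and 14 carried control summits only, 14 in all.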

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

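With 1 library per line, no alternative could leave out a library. The intervals cover counting error only and are narrow. Of 85 alternative values of the main results, 62 fell outside them or, for counts, beyond 1.5 times. The PEG1 share of regions shared stayed below the control share at each distance tried on both references. Nearly as many regions match seen from either list, so the longer list has the lower share. That order repeats the list lengths and is not a separate result. Depth is unknown, so how many of the weaker summits a deeper control library would have shown cannot be read from these lists. Values below are in the order control then PEG1 on B. rapa, then control and PEG1 on B. oleracea. The percentages of summits shared were 56.9, 50.03, 54.8 and 48.96 within 50 bp, 87.3, 76.8, 86.2 and 76.97 within 300 bp, and 96.2, 85.9, 95.4 and 86.3 within 1000 bp. They were 79.9, 71.1, 80.4 and 71.5 with only summits scoring at or above the list median, and 75.96, 75.96, 74.8 and 74.8 with equally long lists. The percentages of regions shared were 82.7, 72.7, 81.1 and 72.5 within 200 bp, 96.1, 85.5, 95.3 and 85.97 within 1000 bp, and 97.6, 88.1, 97.2 and 88.7 within 2000 bp. They were 87.3, 77.8, 88.7 and 78.9 at or above the median score, 88.06, 87.9, 87.6 and 87.6 with equally long lists, and 97.8, 85.02, 93.8 and 87.7 for regions of at least 2 summits. Equal lengths force the shares of both lines together, so that setting says nothing on which line has more. The counts of line-specific regions were 338, 382, 451 and 496 with 0.5 times as many summits from each list, which removes weak summits by construction. Without a summit of the other line within 1000 bp the counts were 1041, 2358, 1672 and 3163, and within 2000 bp they were 570, 1782, 890 and 2382. The median score of shared minus line-specific regions was 11.5, 16.99, 13.8 and 20.4 at 1000 bp. The SD of the PEG1 share over windows was 2.28 and 2.58 percentage points in windows of 200 kb and 1.33 and 1.89 points in windows of 1000 kb on B. rapa and B. oleracea. The runs of line-specific summits were tried at 4 settings, all chosen after the data were seen: they held 1.27 to 2.55 times the permuted mean in PEG1 and 1.47 to 8.21 times in the control, whose counts were 3 to 15. All 46 alternative values of single windows and pseudochromosomes stayed within their intervals, which are too wide for this to say much. The ratio of summits was 1.124 on B. rapa and 1.125 on B. oleracea when each list was cut at its own median, which holds it near its value by construction, and leaving out pseudochromosome 11, chosen after seeing the data, kept it and the shares within their intervals. Restricting the lists to sequences named as chromosomes removed no B. rapa summit and left no B. oleracea summit, and the alternatives for marked genes and gene lists were not run without an annotation of these builds.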

Other observations

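The tests of the splitting of domains, of a segment in 1 line only, of the strength of PEG1-specific summits, of runs against score and of runs of joined specific summits were chosen after the result was seen; those of the detection limit and of runs after joining all PEG1 summits were written before their results. How the tests of runs were weighed against each other was settled after their results were seen.

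H3K4me3 regions were unevenly spread along the B. rapa pseudochromosomes, in the same way in both lines. Leaving out pseudochromosome 11 and the last window of each, the densest 500 kb windows by the regions of both lines together were pseudochromosome 3 from 20500001 to 21000000, with 97 control and 105 PEG1 regions, pseudochromosome 8 from 2500001 to 3000000, with 97 and 104, and pseudochromosome 3 from 17500001 to 18000000, with 95 and 104; the highest PEG1 count, 108, was in another window of pseudochromosome 3, with 90 control regions. The sparsest were the first 500000 bp of pseudochromosome 2, with 3 control and 4 PEG1 regions, pseudochromosome 1 from 23000001 to 23500000, with 7 and 9, pseudochromosome 9 from 16500001 to 17000000, with 9 and 9, and from 27000001 to 27500000, with 8 and 10, and pseudochromosome 1 from 16000001 to 16500000, with 11 and 13. Pseudochromosome 11 held 504 control and 551 PEG1 regions in its first 5 Mb and 65 and 79 in its last 5 Mb of full windows. It exceeds the 10 chromosomes of B. rapa and its make-up is not given in the sources used here, so this gradient is not read as that of a chromosome. Across windows the counts of the lines correlated with r = 0.972 on B. rapa and 0.976 on B. oleracea, over windows of one genome, which are not replicates.

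Within the shared summits the order of the scores was similar but not equal. Across 21881 pairs on B. rapa Spearman's rho was 0.84, and across 28084 pairs on B. oleracea 0.854, over pairs of summits, which are not independent replicates. The rank percentile differed by over 50 points in 0.507% of the B. rapa pairs, 52 ranked higher in PEG1 and 59 in the control, and in 0.317% of the B. oleracea pairs, 49 and 40. These percentiles were taken among the shared pairs of a reference and not in the whole lists. The most unequal pairs in each direction were chosen after their values were seen. On pseudochromosome 1 the summit at 22257041 stood at percentile 7.20 by control and 76.9 by PEG1 score, and that at 19876902 at 83.9 and 12.6. The summit on scaffold ERB29325 at 39242 stood at 12.9 and 84.8, and that on scaffold ERB29668 at 309925 at 84.5 and 6.31. Without replicate libraries none of these can be set against the spread of a line.

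The longer PEG1 lists were the main difference between the lines. Domains called as 1 peak in the control and as several in PEG1 could add summits, but 71.0% of the excess on B. rapa (2692 of 3792) and 74.1% on B. oleracea (3214 of 4336) was left when only summits over 2000 bp from any of the other line were counted, which argues against splitting as the whole cause. A segment of up to 10% of the reference carried by PEG1 only, as the whole cause, is argued against on B. rapa. There 77.7% of the excess of regions was left outside the 10% of 500 kb windows where it was largest (2848 of 3667). On B. oleracea 60.6% was left (2537 of 4189, counting error 5.77 points), so the excess was not confined to those windows. The test required over 50% to be left after a margin for counting error, and with that margin this share fell just short. For a segment of that size the B. oleracea test therefore does not decide. Many windows on B. oleracea hold short scaffolds, so 10% of the windows is also not 10% of the reference. Smaller segments as part of the cause stay open: 0 stretches on B. rapa and 0 on B. oleracea held 10 or more regions of one line between neighbouring regions of the other, but reads from the other subgenome could have kept part of a segment marked. A lower detection limit in the PEG1 library, from depth or from a better enrichment, is a candidate explanation: 32.6% of the PEG1 summits over 2000 bp from any control summit on B. rapa (31.1 to 34.3) and 35.6% on B. oleracea (34.2 to 37.1) scored above the median of PEG1 summits whose control partner was in the weakest 10% of its list, and 2.08% and 1.19% of them scored above the median of the whole list, where 50% would if they were as strong as the rest. Of control summits over 2000 bp from any PEG1 summit, 2.28% on B. rapa and 1.01% on B. oleracea scored above the median of their list. Such weakness was therefore not particular to PEG1. Of PEG1 summits unmatched at 500 bp, 8.14% and 7.91% scored above the median of their list, and of control summits 15.5% and 13.9%. A true difference in H3K4me3 at weakly marked loci between the lines would look alike and cannot be told apart from it with 1 library per line.

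Whether summits of PEG1 with no control summit within 1000 bp lay beside one another more often than their scores would give was not settled. In runs of 3 or more neighbouring summits stood 352 of 4450 on B. rapa and 352 of 5577 on B. oleracea, against means of 245.0 and 274.8 when the specific label was permuted 1000 times within 20 score classes, and 0 and 1 of the permutations reached the observed number. Of the control-specific summits 12 of 1044 and 15 of 1682 stood in such runs, against means of 4.38 and 10.2, with 66 and 238 of the permutations as high. Summits close together share their distance to the other line, so these permutations can understate chance and do not by themselves exclude score alone. How far they understate it was not measured. Pieces of single enriched domains are a candidate explanation: after joining all PEG1 summits within 2000 bp, 132 of 3119 and 150 of 3941 specific regions stood in runs, against means of 133.1 and 139.7, and 540 and 302 of the permutations were as high. With only specific neighbours within 2000 bp counted as 1, 175 of 4220 and 176 of 5283 groups stood in runs, against means of 128.8 and 138.6, with 11 and 35 of the permutations as high. The same joining with specificity at 2000 bp left 128 and 144 groups in runs against means of 52.2 and 56.5, with 0 permutations as high on either reference. These settings thus went the same way. Only the test that joined all PEG1 summits, shared ones included, differed, so the tests disagree on how joining is done. Over the 4 settings tried without joining shared summits (specific at 1000 or 2000 bp, with or without counting specific neighbours as 1), 0 to 11 permutations were as high for PEG1 on B. rapa and 0 to 35 on B. oleracea, and 25 to 175 and 231 to 407 for the control. The longest PEG1 run held 6 summits over 34.0 kb on B. rapa, and a longest one on B. oleracea held 5 over 51.5 kb. At these lengths neither run could be joined to 1 region within 2000 bp. These runs were picked for their length and do not speak for the rest. Permutations gave runs of up to 9 and 8 summits. Those are the highest values over all 1000 permutations, so they do not show how often chance reaches the observed lengths. A difference in the mark between the lines as the cause of the runs was not tested and stays open.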
